A study of Mus musculus with 18 samples.

How the data were processed

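Total RNA from mouse stem cell cultures was measured on Affymetrix Mouse Gene 1.0 ST arrays, which read each gene as a probe set, a group of short probes along its transcript. The labels place the 18 arrays in 6 groups of 3 biological replicates. They are undifferentiated embryonic stem (ES) cells and adult stem cells of the 129SV background, the same cell types of the Stra8-EGFP/Rosa26 background (called Stra8 here), and differentiated ES and adult cells of the 129SV background. The adult cells are named in the series title as adult germline stem cells. RNA was isolated with Trizol and treated with DNase I, and 300 ng was labelled with biotin, per the labels' protocols. The labels state neither how the cells were differentiated, nor whether they grew on feeder cells, nor how many lines or cultures stand behind the replicates, nor any date of hybridisation. The p-values therefore measure the spread between samples that the labels call biological replicates.

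The deposited values are log2 signals that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes, which give no version. RMA corrects the background, brings the arrays to a shared distribution and summarises the probes of each probe set on the log2 scale. Whether all 18 arrays were normalised together is not stated. The values were used as deposited, with no further scaling. They ran from 1.27 to 14.6, which fits a log2 scale, and were not centred per gene. The medians over all probe sets were 7.22, 7.23 and 7.22 in ES 129SV, 7.26, 7.28 and 7.25 in adult 129SV, and 7.27, 7.28 and 7.28 in ES Stra8. They were 7.27, 7.27 and 7.27 in adult Stra8, 7.35, 7.35 and 7.35 in differentiated ES 129SV, and 7.36, 7.35 and 7.38 in differentiated adult 129SV. No scanner output, detection call or background level was available, so no value could be set against background. The number of arrays, 3 per group, limits the precision.

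Probe sets were named from the platform annotation. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not named. Of the named ones, 21698 matched a RefSeq gene ID of mouse assembly GRCm38.p6, and no symbol changed on matching. Probe sets with several symbols or none stayed out of the gene tests. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all 18 arrays was used, which left 19938 genes. Where the probe sets of such a gene were tested separately, between 1 and 41 of the 999 genes per comparison had probe sets called in opposite directions. None of them is among the genes that the rule below names for the same comparison. Genes named outside that rule were not checked. Genes without a probe set of their own symbol, such as H19 and Ddx3y, were not analysed here.

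One linear model with a mean per group was fitted to all 18 arrays with limma (lmFit and eBayes), which shares 1 estimate of the spread over the groups with 12 residual and 3.78 prior degrees of freedom. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over the 19938 genes within each comparison), and a stricter count also required a log2 change of at least 1, which is 2-fold. Changes are differences of group means of log2 values. Where a standard error (SE) is given, it uses the spread shared over all groups and not that of the compared groups alone. The 7 comparisons of group pairs were adult against ES cells in each background and after differentiation, differentiated against undifferentiated cells for each origin, and Stra8 against 129SV for each origin. Both differences between such effects were tested as interactions: the effect of origin between backgrounds, and the response to differentiation between origins. Pearson correlations between arrays, over the genes tested, and the share of genes whose 95% confidence interval lay within a 2-fold change gave the size of the differences between groups. Principal components were computed on the gene-centred values.

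The comparisons, tests, gene lists and alternatives were fixed before the data were examined. The 20 lists held genes of pluripotency, the primed epiblast, spermatogonial stem cells, germline and meiosis, paternally and maternally expressed imprinted genes, neural ectoderm, mesoderm, endoderm and extraembryonic tissue, trophectoderm, Hox genes, the retinoid response, the 2-cell-like state, the Y chromosome, fibroblasts (as used for feeder layers), somatic cells of the testis, macrophages and blood, the cell cycle, stress and immediate-early genes, and chromatin and DNA methylation. Of the 429 genes listed, 396 were measured. Lists were tested with camera from limma at a preset correlation between genes of 0.01, with adjustment over the 180 tests of 20 lists in 9 comparisons. The alternatives were a correlation estimated from the data and fry. For fry, the p-value used asks whether the genes of a list move, on balance, in the same direction, and it does not compare them with other genes. Camera called 68 of the 180 tests. With an estimated correlation 40 of these calls held, and calls lost that way or with dim genes left out are named where they are reported. All 68 also passed fry. Lists of 34 interferon-induced genes, 29 hypoxia-induced genes and 42 transcripts of the Dlk1-Dio3 region were written after the named genes had been seen.

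The genes named in the text follow a fixed rule. For each comparison of 2 groups they are the 10 highest and 10 lowest log2 changes among called genes whose groups do not overlap, leaving out predicted genes, and for each interaction the 6 highest and 6 lowest. Up to 4 members of each list with the smallest adjusted p were added, and Pou5f1, Nanog, Sox2, Klf4, Zfp42, Stra8, Gfra1, Ddx4, Dazl, Igf2 and Xist were always given, called or not. Exceptions chosen after their values were seen are Car4, and in the closing section the members named from the maternally expressed imprinted, fibroblast, hypoxia and Dlk1-Dio3 lists.

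The fit was tested on simulated values drawn around each gene's mean with its residual spread in the real arrays, with 50 genes changed at each size. For adult against ES 129SV cells it recovered 22% of genes changed by 0.3 on the log2 scale, 66% at 0.5, 100% at 1 and 100% at 2, and called 3 of 19738 unchanged genes. For adult against ES Stra8 cells the shares were 28%, 70%, 100% and 100% with 5 unchanged genes called. For differentiation of ES cells they were 26%, 78%, 100% and 100% with 8 called, and for the difference between backgrounds 2%, 38%, 98% and 100% with 4 called. With no list changed, 5 of 180 camera tests had an unadjusted p under 0.05, and a list of 37 genes shifted by 0.5 was called. Far fewer genes changed here than were called in the real data, which makes the adjusted threshold stricter. The shares recovered are therefore not the sensitivity of the real comparisons. Genes were drawn independently, so the camera result does not show its error rate where genes correlate.

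The alternatives were a fit to the arrays of the compared groups alone, the replicate number as a block, eBayes with trend and robust options, array weights, centring each array on its median, a further quantile normalisation, leaving out dim genes, averaging the probe sets of a gene, testing every probe set, and leaving out each array in turn. The dim genes were those whose highest group mean lay under 7.61, the median of all gene values, and 11491 genes remained. The replicate numbers are shared by all groups. In differentiated adult against ES cells, arrays with the same number deviated together from their group means in each of the 3 pairs (r across genes 0.153, 0.144 and 0.442), so the numbers were taken to pair the samples there. This pairing comes from the values and not from the labels, and only 1 of the 3 adult arrays correlated best with the ES array of its own number. No 2 arrays held the same values: the most alike pair, ES Stra8 replicates 1 and 3, had a standard deviation of differences of 0.139 over 19938 genes, and 9 of these genes had exactly the same deposited value in both, with no tolerance. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.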

Results

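Gene expression was measured in undifferentiated mouse ES cells and adult germline-derived stem cells of the 129SV and Stra8 backgrounds, and in differentiated ES and adult cells of the 129SV background, with 3 arrays in each of the 6 groups. Stra8 is a gene that retinoic acid induces in germ cells before meiosis. The title of the series states the question, which is how similar the transcriptomes of both stem cell types are, with genes linked to pluripotency named among them. Each array was hybridised from 300 ng of RNA. Values are on the log2 scale, and each change is given with its SE from 3 arrays per group.

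Undifferentiated and differentiated cells formed the main division among the 18 arrays. The first principal component held 57.9% of the variance, and the following 3 held 13.8%, 12.6% and 5.4%. Arrays of the same group correlated with a mean r across genes between 0.993 and 0.998. Between ES and adult cells the mean r was 0.971 in the 129SV background, 0.990 in the Stra8 background and 0.985 after differentiation. ES 129SV cells had a higher mean r with adult Stra8 cells (0.979) than with ES Stra8 cells (0.972) or adult 129SV cells (0.971). Differentiation lowered the mean r to 0.933 for ES and 0.939 for adult cells. With genes left out that were dim in every group, the mean r was 0.904, 0.971 and 0.958 between ES and adult cells, and 0.762 and 0.792 across differentiation. Replicate 3 of differentiated ES 129SV stood apart, with a mean r of 0.992 to its group and an array weight of 0.153.

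**Figure D1:**
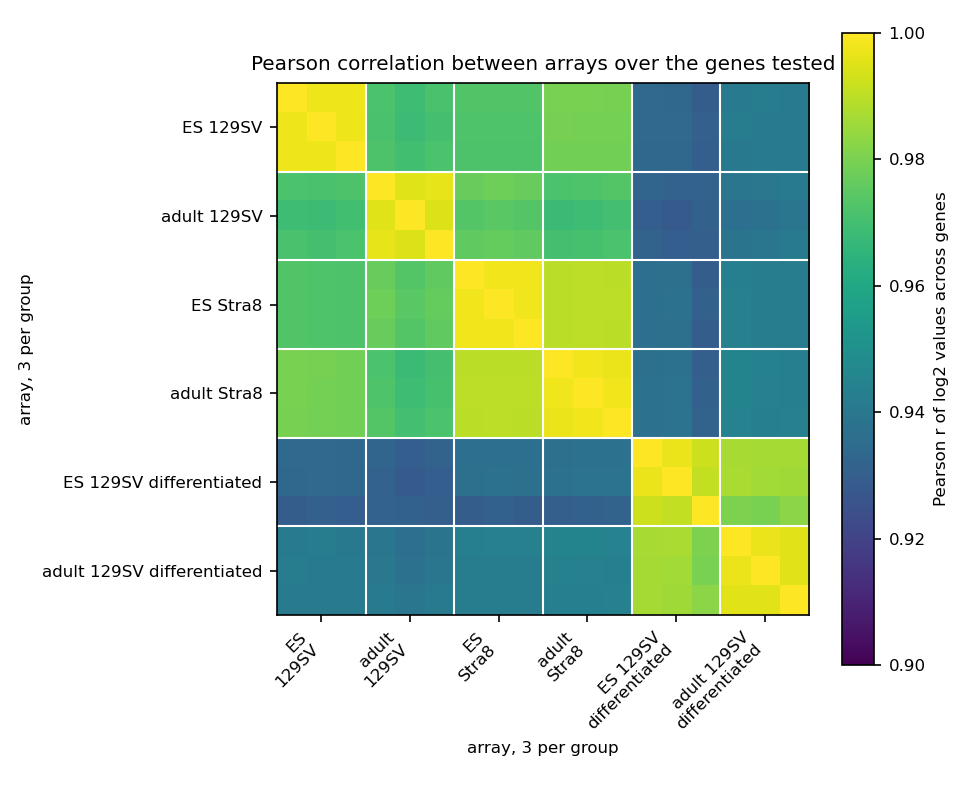
Pearson r across 19938 genes between each pair of the 18 arrays, ordered by group. Colours run over the range of r, and the mean r between undifferentiated and differentiated cells of the same origin was 0.933 for ES and 0.939 for adult cells.

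Adult 129SV stem cells had lower levels of interferon-induced genes than ES 129SV cells. The 10 largest decreases were all in genes of this kind, among them the chemokine Cxcl10 (-5.85 ± 0.08, adjusted p = 9.10e-17), the antiviral gene Ifit3 (-5.62 ± 0.09) and Irf7, a transcription factor that drives interferon production (-5.22 ± 0.09, adjusted p = 2.94e-16). Dppa3, a regulator of DNA methylation in early embryos and germ cells, was higher in adult cells by 2.39 ± 0.11 (adjusted p = 2.86e-11). So were the autophagy receptor Calcoco2 (2.68 ± 0.13), the neuronal tubulin Tubb3 (1.83 ± 0.09), the germ cell gene Tex19.1 (1.55 ± 0.10) and the Nodal antagonist Lefty1 (1.51 ± 0.09). All 3 adult arrays lay on the same side of all 3 ES arrays for each of these genes. In a list of 34 interferon-induced genes written after these values were seen, and so not independent evidence, all 34 were lower, with a median change of -2.71.

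The pluripotency list went both ways in this comparison. Of its 29 measured genes 7 were higher, 8 were lower and 14 did not pass, with the same counts adjusted over the list alone. Its median (0.01) and mean (0.04) were positive while camera gave the direction down (adjusted p = 0.881). The change was -0.04 ± 0.10 for Pou5f1 (adjusted p = 0.787), -0.10 ± 0.05 for Nanog (0.115), -0.18 ± 0.11 for Sox2 (0.186) and 0.34 ± 0.15 for Zfp42 (0.0787), and none of these passed. Klf4 fell by 0.17 (adjusted p = 0.0325), and Nr0b1, an orphan nuclear receptor of the pluripotency network, fell by 1.19. Among germ cell genes, the change of Stra8 was 0.03 ± 0.12 (0.840) and that of the helicase Ddx4 0.04 ± 0.08 (0.731), while the RNA-binding protein Dazl fell by 1.53 and the GDNF receptor Gfra1 by 0.60. The growth factor Igf2 fell by 0.65 and Xist, the RNA of X inactivation, by 1.19.

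Fibroblast genes were lower in adult 129SV cells: 17 of 22 fell and 2 rose, with the same counts adjusted over the list alone (median -0.81, camera adjusted p = 5.95e-09). The collagen-binding proteoglycan Dcn fell by 2.52, the mesenchymal transcription factor Prrx1 by 1.45 and collagen Col5a2 by 1.34. In the endoderm and extraembryonic list 15 of 27 fell and 0 rose (15 and 1 adjusted over the list alone, median -0.33, adjusted p = 0.000372), with the endocytic receptor Cubn at -2.29 and thrombomodulin, Thbd, at -1.54. Stress and immediate-early genes fell in 12 of 18 members and rose in 2 (13 and 2 adjusted over the list alone, median -0.72, adjusted p = 8.20e-05), among them the amino acid stress genes Chac1 (-1.87), Trib3 (-1.15) and Asns (-0.88). Trophectoderm genes rose in 9 of 16 and fell in 1 (the same adjusted over the list alone, median 0.32, adjusted p = 0.00904), among them the keratins Krt18 (0.93) and Krt7 (0.85). Maternally expressed imprinted genes fell in 8 of 19 and rose in 2, also when adjusted over the list alone (median -0.09, adjusted p = 0.0408), and their call was lost with adjusted p = 0.407 with an estimated correlation and 0.123 with dim genes left out. The growth inhibitor Grb10 fell by 1.54 and Igf2r, the receptor that clears Igf2, by 0.73.

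Among the lists without a call, retinoid response genes fell in 8 of 15 and rose in 2 (median -0.29, adjusted p = 0.0586), and cell cycle genes rose in 11 of 26 and fell in 3 (median 0.13, 0.0872), also adjusted over the list alone for the former and 12 and 3 for the latter. Spermatogonial stem cell genes rose in 8 and fell in 5 of 19, also adjusted over the list alone, with a median of 0.02, a mean of -0.08 and a camera direction of down (adjusted p = 0.851). Germline and meiotic genes rose in 7 and fell in 13 of 33 (7 and 14 adjusted over the list alone), with a median of 0.04 and a mean of -0.20 (direction down, 0.352). For genes of neural ectoderm the counts were 7 and 6 of 23 (median 0.13, 0.623), for somatic cells of the testis 4 and 1 of 14 (median 0.14, 0.222), and for the 2-cell-like state 1 and 1 of 5 (median 0.22, 0.944). Adjusted over the list alone these counts were the same for the neural and testis lists, and 2 and 1 for the 2-cell-like list. Camera called none of these 3 lists in any of the 9 comparisons, except that the testis list was called between the backgrounds of ES cells when dim genes were left out (adjusted p = 0.0421).

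In total 9196 of 19938 genes were called between adult and ES 129SV cells, 4583 higher and 4613 lower, a balance that turned with arrays centred (5288 and 4319) or quantile normalised (5450 and 4226). At least 2-fold were 785, 101 higher and 684 lower, or 168 and 599 after quantile normalisation and 456 and 1106 with every probe set tested. For 93.2% of genes the confidence interval lay within a 2-fold change. The call of Klf4 was lost without ES replicate 1 (adjusted p = 0.0629) or 2 (0.130), or without adult replicate 1 (0.103) or 2 (0.0952), in a fit to these 6 arrays alone (0.0586), and after quantile normalisation, where the change was -0.06 (0.512). Sox2 (0.0280) and Zfp42 (0.00244) were called in the fit to these 6 arrays alone, Zfp42 also after quantile normalisation (0.43, adjusted p = 0.0250). Nanog was called without adult replicate 3 (-0.14, adjusted p = 0.0497).

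Adult Stra8 cells were compared with ES cells of their own background. The proteoglycan core protein Srgn was higher by 3.90 ± 0.08 (adjusted p = 2.77e-14), Cubn by 3.20 ± 0.07 (5.62e-14) and the tetraspanin Tspan8 by 2.26 ± 0.08. Genes of the germ line stood among the 10 highest: Cyct, a testis form of cytochrome c (2.14 ± 0.14), Scml2, a Polycomb protein of the male germ line (1.95 ± 0.11), and Mael, which silences transposons in germ cells (1.82 ± 0.10). The ectonucleotidase Enpp3 was lowest (-2.31 ± 0.08, adjusted p = 2.72e-11), followed by Pnma5 (-1.81) and Trim12a (-1.78), and the Hedgehog-binding protein Hhip fell by 1.36. The 3 adult arrays did not overlap the 3 ES arrays for any of these genes.

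Pluripotency genes were lower in adult Stra8 cells, with 18 of 29 down and 2 up (19 and 2 adjusted over the list alone, median -0.34, camera adjusted p = 5.35e-08). Nanog fell by 0.74 (adjusted p = 2.40e-08), Prdm14, a repressor that guards the naive state, by 0.86 and Dppa4 by 0.91. Zfp42 fell by 0.65 (0.00318), Klf4 by 0.39 (0.000153) and Sox2 by 0.34 (0.0273). The change of Pou5f1 was -0.02 ± 0.10 (0.920). Genes of the primed epiblast rose in 5 of 12 and fell in 1 (6 and 1 adjusted over the list alone, median 0.16, adjusted p = 0.0198), led by the DNA methyltransferase Dnmt3b (1.44), and this call was lost with adjusted p = 0.298 with an estimated correlation. Germline and meiotic genes rose in 16 of 33 and fell in 7, also adjusted over the list alone (median 0.09, adjusted p = 0.00286), a call that was lost when dim genes were left out (0.0540). The synaptonemal complex gene Sycp1 rose by 1.46 and the meiotic cohesin Smc1b by 1.10, while Sycp3 fell by 1.52. Ddx4 rose by 0.58, Dazl by 0.47 and Gfra1 by 0.29 (adjusted p = 0.0215), and Stra8 itself changed by 0.03 ± 0.12 (0.926).

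Every measured fibroblast gene was higher in adult Stra8 cells, 22 of 22 over all genes and adjusted over the list alone (median 0.73, adjusted p = 2.88e-22), among them smooth muscle actin, Acta2 (1.08), Col5a2 (1.08) and Prrx1 (0.95). The endoderm and extraembryonic list rose in 18 of 27 with 0 down (19 adjusted over the list alone, median 0.44, adjusted p = 8.41e-12), with the endocytic adaptor Dab2 at 1.31 and the matrix protein Sparc at 0.91. Hox genes, which pattern the body axis, rose in 15 of 37 with 0 down (18 adjusted over the list alone, median 0.22, adjusted p = 1.51e-05), led by Hoxc6 (0.72). Retinoid response genes rose in 8 of 15 with 0 down, also adjusted over the list alone (median 0.30, adjusted p = 0.000434), led by the retinaldehyde reductase Dhrs3 (0.88). Y-linked genes rose in 4 of 7, also adjusted over the list alone (median 0.29, adjusted p = 0.0390), with Uty at 1.18, and the call was lost with adjusted p = 0.0982 with an estimated correlation and 0.0522 with dim genes left out. Igf2 rose by 1.19 and Xist by 0.64.

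Between adult and ES Stra8 cells 5638 genes were called, 2635 higher and 3003 lower, and 150 changed at least 2-fold, 97 higher and 53 lower (136 and 242 with every probe set tested); the confidence interval of 98.1% of genes lay within a 2-fold change. With array weights the count was 8690. Sox2 was no longer called without any 1 of ES replicates 1 (adjusted p = 0.0589), 2 (0.0647) or 3 (0.0773) or adult replicates 2 (0.0674) or 3 (0.0920), and Gfra1 was not without ES replicates 1 (0.0667) or 2 (0.0638) or adult replicates 1 (0.0571), 2 (0.0510) or 3 (0.0570).

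**Figure D2:**
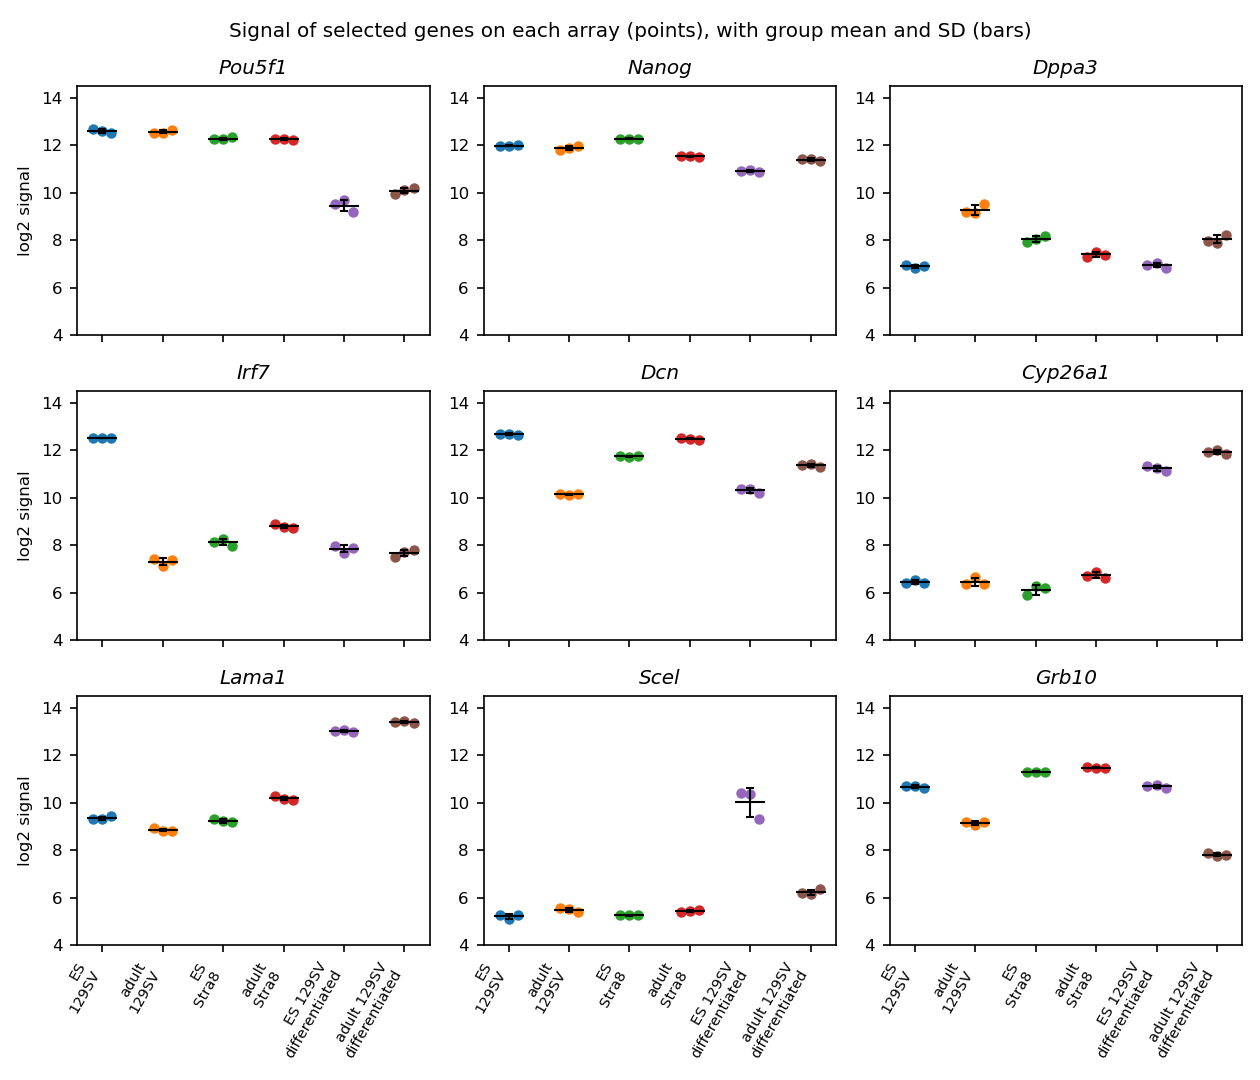
Log2 signal of 9 genes in each of the 18 arrays, with points for arrays and bars for the mean and SD of 3 arrays per group. Irf7 in adult 129SV cells differed from ES 129SV cells by -5.22, while Pou5f1 differed by -0.04 between the same groups.

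The difference between adult and ES cells, called the effect of origin here, went in opposite directions in both backgrounds for many genes. It may also hold differences of line, culture or cell mix, which the labels do not settle. The fibroblast list was among those that went opposite ways, with medians of -0.81 in 129SV and 0.73 in Stra8 cells. Tested as a difference between backgrounds (Stra8 minus 129SV), Cxcl10 (6.29 ± 0.12), Ifit3 (6.01 ± 0.13), Irf7 (5.89 ± 0.13), Srgn (6.07 ± 0.11) and Cubn (5.49 ± 0.10) were the most positive with Ifit3b (5.46 ± 0.17). Calcoco2 (-3.71 ± 0.18), Dppa3 (-3.05 ± 0.15), Tubb3 (-2.74 ± 0.12) and Enpp3 (-2.68 ± 0.12) were the most negative with Pnma5 (-2.60) and AU015836 (-2.55). Nanog (-0.64, adjusted p = 1.34e-06) and Zfp42 (-0.99, 0.00101) differed between backgrounds, as did Gfra1 (0.89), Ddx4 (0.54), Dazl (2.01), Igf2 (1.85) and Xist (1.84). The difference was 0.01 ± 0.14 for Pou5f1 (0.952), -0.15 ± 0.15 for Sox2 (0.469), -0.22 ± 0.09 for Klf4 (0.0566) and -0.01 ± 0.17 for Stra8 (0.978).

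Fibroblast genes were positive in 20 of 22 and negative in 1 (21 and 1 adjusted over the list alone, median 1.53, camera adjusted p = 7.57e-16), with Dcn at 3.27 and Prrx1 at 2.40. The endoderm and extraembryonic list was positive in 16 of 27 with 0 negative, also adjusted over the list alone (median 0.78, 1.34e-07), and the stress list in 12 of 18 with 1 negative (12 and 2 adjusted over the list alone, median 0.62, 0.00126). The pluripotency list was negative in 13 of 29 and positive in 4 (15 and 4 adjusted over the list alone, median -0.24, 0.0236), with adjusted p = 0.177 with an estimated correlation. Retinoid response genes were positive in 8 of 15 and negative in 2 (9 and 2 adjusted over the list alone, median 0.53, 0.00629), with adjusted p = 0.0886 with an estimated correlation and 0.0590 with dim genes left out. Hox genes were positive in 10 of 37 with 0 negative, also adjusted over the list alone (median 0.18, 0.0405), with adjusted p = 0.221 with an estimated correlation and 0.184 with dim genes left out. Germline and meiotic genes were positive in 15 of 33 and negative in 5 (15 and 6 adjusted over the list alone, 0.0413), with adjusted p = 0.150 with an estimated correlation and 0.136 with dim genes left out; their median of 0.01 turned to -0.03 when arrays were centred. The transposon silencer Mael (3.02) and the cohesin Stag3 (1.22) were among the positive ones.

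Of 8588 genes whose effect of origin differed between backgrounds, 4243 were positive and 4345 negative, and 1719 differed at least 2-fold, 1261 positive and 458 negative (1808 and 1290 with every probe set tested). Klf4 was called with the replicate number as a block (adjusted p = 0.0465), in a fit to these 12 arrays alone (0.0368), with arrays centred (0.0125) or quantile normalised (0.0215), and without ES 129SV replicate 2 (0.0430). Genes called in both backgrounds numbered 3936, of which 979 had the same sign and 2957 opposite signs, against 1299.9 opposite ones for independent calls. Higher in both were 348 genes against 606 for independent calls (Fisher's exact test over genes, two-sided p = 1.96e-41), and lower in both were 631 against 695 (p = 0.00265), with genes not being independent replicates. The changes correlated across genes with r = -0.36 (Spearman -0.26). Car4, a membrane-bound carbonic anhydrase, was the 1 gene changed at least 2-fold the same way in both, by 1.02 and 1.73, and is named outside the rule for the 129SV background. With array weights the count of the same sign was 1714.

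Differentiation of ES 129SV cells lowered pluripotency genes and raised genes of endoderm, extraembryonic tissue, trophectoderm and the retinoid response. Pou5f1 fell by 3.14 (adjusted p = 5.06e-14), Sox2 by 2.14, Zfp42 by 1.84 and Nanog by 1.07, while Klf4 changed by 0.00 ± 0.06 (0.956). The highest genes were the uroplakin Upk1b (5.32 ± 0.10, adjusted p = 9.10e-17), the glucuronosyltransferase Ugt2b34 (5.19 ± 0.15), the water channel Aqp8 (5.05 ± 0.11), the stomach protein Gkn2 (4.96 ± 0.09) and Cyp26a1, which degrades retinoic acid (4.80 ± 0.11). The lowest were the matrix metalloproteinases Mmp13 (-7.33 ± 0.08, adjusted p = 5.63e-19) and Mmp3 (-6.79 ± 0.05), the cytokine Il6 (-6.40 ± 0.13) and Inhba, a subunit of activin (-5.41 ± 0.07). The fibroblast list fell in the same comparison (median -1.91). Whether these decreases came from a smaller share of fibroblast-like cells was not tested. All 3 arrays of each group were apart from the other group for these highest and lowest genes.

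Of the 29 pluripotency genes 26 fell and 0 rose, also adjusted over the list alone (median -1.84, camera adjusted p = 5.17e-14), among them the Nodal co-receptor Tdgf1 (-4.19), Nr0b1 (-4.03) and Utf1 (-3.59). The endoderm and extraembryonic list rose in 22 of 27 and fell in 2 (23 and 2 adjusted over the list alone, median 1.71, 1.22e-09), among them the laminin chains Lama1 (3.68) and Lamc1 (2.03). Trophectoderm genes rose in 13 of 16 and fell in 1 (14 and 1 adjusted over the list alone, median 1.03, 2.29e-05), with Krt18 at 3.69, Krt7 at 3.65 and the transcription factor Gata3 at 2.94. Retinoid response genes rose in 11 of 15 and fell in 2, also adjusted over the list alone (median 1.37, 8.74e-05), with transglutaminase 2, Tgm2, at 2.54. Paternally expressed imprinted genes rose in 13 of 21 and fell in 4, also adjusted over the list alone (median 0.54, 0.00172), among them the zinc finger genes Peg3 (3.72) and Plagl1 (2.85) and Igf2 (2.07). Hox genes rose in 21 of 37 and fell in 6, also adjusted over the list alone (median 0.35, 0.0405), with adjusted p = 0.221 with an estimated correlation, and Hoxa5 rose by 1.80.

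Fibroblast genes fell in 20 of 22 and rose in 1, also adjusted over the list alone (median -1.91, adjusted p = 6.45e-13), with Prrx1 at -5.29 and the surface protein Thy1 at -3.89. Cell cycle genes fell in 21 of 26 and rose in 1, also adjusted over the list alone (median -0.83, 1.99e-08), among them the ribonucleotide reductase subunit Rrm2 (-1.88) and the replication helicase Mcm5 (-1.80). Germline and meiotic genes fell in 20 of 33 and rose in 5, also adjusted over the list alone (median -0.43, 0.00332), with Syce2 of the synaptonemal complex at -1.84 and the meiotic cohesin Rec8 at 1.60. Genes of chromatin and DNA methylation fell in 16 of 22 and rose in 2 (16 and 3 adjusted over the list alone, median -0.89, 1.85e-05), with Dnmt3l at -3.78 and Dnmt3b at -2.93, and their call was lost with adjusted p = 0.106 with an estimated correlation. Stra8 rose by 0.49 (adjusted p = 0.00254) and Dazl by 0.47, Ddx4 (-0.54) and Xist (-3.26) fell, and Gfra1 changed by 0.02 ± 0.09 (0.852). In all, 11005 genes were called, 5553 higher and 5452 lower. This balance turned with array weights (6371 and 6557), dim genes left out (4340 and 4849) or the compared arrays alone (4880 and 4947). At least 2-fold were 2316, 961 higher and 1355 lower (2081 and 1806 with every probe set tested).

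Differentiation of adult 129SV cells raised genes of the retinoid response. Ugt2b34 (6.11 ± 0.15), Cyp26a1 (5.47 ± 0.11, adjusted p = 3.81e-16), Aqp8 (5.23 ± 0.11), Srgn (5.19 ± 0.08), Cubn (5.07 ± 0.07) and Lama1 (4.54 ± 0.06, adjusted p = 1.28e-17) were among the 10 highest. Mmp3 (-4.59 ± 0.05, adjusted p = 6.72e-19), the neutrophil chemokine Cxcl5 (-4.51 ± 0.10), Mmp13 (-4.49 ± 0.08) and the BMP antagonist Grem1 (-3.45 ± 0.11) were among the 10 lowest. Pou5f1 fell by 2.47 (adjusted p = 1.23e-12), Sox2 by 1.53, Zfp42 by 1.38 and Nanog by 0.49, while Klf4 rose by 0.33 (0.0002). The germ cell genes Dazl (2.69) and Stra8 (0.97) rose and Ddx4 fell by 0.71, and these highest and lowest genes did not overlap between the groups of 3 arrays.

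The pluripotency list fell in 25 of 29 and rose in 2, also adjusted over the list alone (median -1.38, camera adjusted p = 5.81e-10), with Lefty1 at -2.70 and Tdgf1 at -2.58. Retinoid response genes rose in 11 of 15 and fell in 2, also adjusted over the list alone (median 2.50, 6.01e-05), among them Dhrs3 (3.72), the homeobox gene Meis2 (3.61) and the retinol transporter Stra6 (3.37). The endoderm and extraembryonic list rose in 18 of 27 and fell in 3 (19 and 3 adjusted over the list alone, median 2.48, 8.82e-09), with Dab2 at 3.33. Cell cycle genes fell in 20 of 26 and rose in 2, also adjusted over the list alone (median -0.60, 1.27e-05), led by cyclin D1, Ccnd1 (-2.45). Trophectoderm genes rose in 10 of 16 and fell in 3, also adjusted over the list alone, without a call (median 0.40, adjusted p = 0.0538). Of 18 stress and immediate-early genes 10 rose and 4 fell, also adjusted over the list alone, without a call (median 0.23, 0.0683), although the transcription factor Fos rose by 2.55.

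Several calls of this comparison were lost with an estimated correlation. In adult cells, primed epiblast genes fell in 10 of 12 with 0 up (median -0.48, adjusted p = 0.00299), with adjusted p = 0.198 with an estimated correlation. Paternally expressed imprinted genes rose in 13 of 21 and fell in 4 (median 0.26, 0.0155), with adjusted p = 0.102 with an estimated correlation and 0.0608 with dim genes left out, and the noncoding RNA Airn rose by 4.22. Fibroblast genes fell in 15 of 22 and rose in 6 (median -0.59, 0.0408), with adjusted p = 0.221 with an estimated correlation and 0.0649 with dim genes left out; Prrx1 fell by 3.13 while the metalloproteinase Mmp2 rose by 2.57. Chromatin and DNA methylation genes fell in 17 of 22 and rose in 3 (median -0.55, 0.000134), with adjusted p = 0.150 with an estimated correlation. Adjusted over the list alone the counts of these 4 lists were the same. Igf2 rose by 0.67, Xist fell by 2.02 and Gfra1 rose by 0.27 (adjusted p = 0.0152), a call that was lost without adult replicate 1 (0.0587) or 2 (0.0856). In all, 11906 genes were called, 5478 higher and 6428 lower, a balance that turned with dim genes left out (4882 and 4640). At least 2-fold were 2371, 1502 higher and 869 lower (3432 and 1324 with every probe set tested).

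Both differentiations moved genes largely in the same direction. Of 8453 genes called in both, 7239 had the same sign and 1214 opposite signs. Higher by at least 2-fold in both were 657 genes against 72.4 for independent calls, and lower were 534 against 59.1. The fibroblast list fell in both, with medians of -1.91 in ES and -0.59 in adult cells. A shared loss of fibroblast-like cells was not tested. The changes correlated across genes with r = 0.67 (Spearman 0.59).

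**Figure D3:**
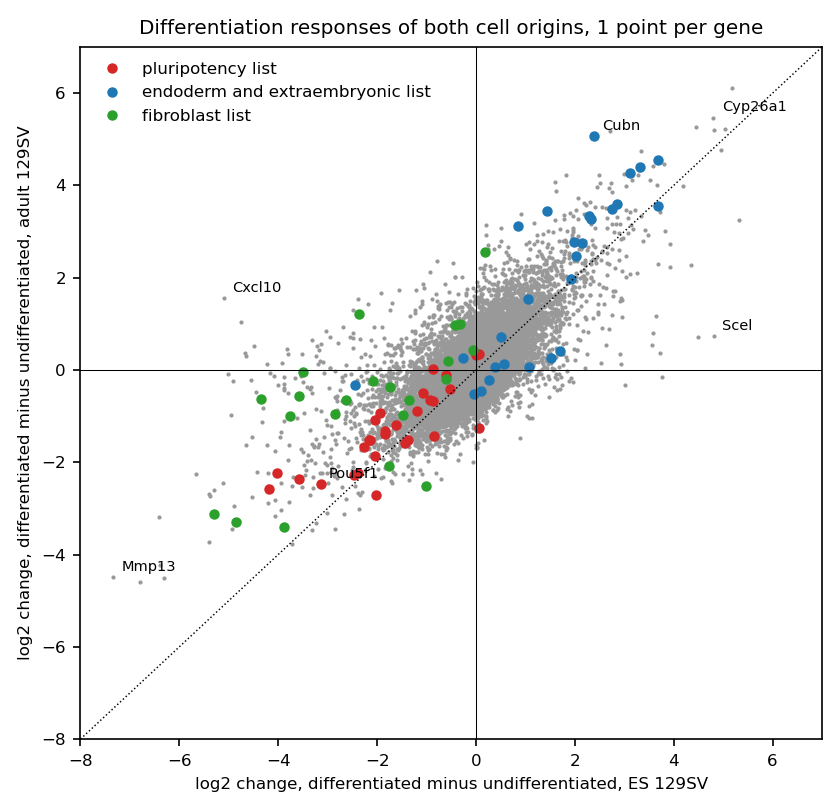
Log2 change on differentiation of each gene in ES 129SV cells (horizontal) and adult 129SV cells (vertical), with the dotted line where both are equal and the pluripotency, endoderm and fibroblast lists in colour. Pou5f1 fell by 3.14 and 2.47 and Cyp26a1 rose by 4.80 and 5.47, while Cxcl10 lies above the line with a difference of 6.66.

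The response differed with origin for 9110 genes, tested as adult minus ES. A gap between the undifferentiated groups counts in this test too, and the same gap counts in the difference between backgrounds. Cxcl10 had means of 13.14 in ES and 7.295 in adult 129SV cells, against 8.04 and 8.855 after differentiation. The most positive differences were those of the interferon-induced genes Cxcl10 (6.66 ± 0.12), Ifit3 (5.80 ± 0.13), Irf7 (5.04 ± 0.13), Iigp1 (5.02 ± 0.21), Ifit3b (4.95 ± 0.17) and Trim30a (4.92 ± 0.23). The most negative were those of Scel, a protein of cornifying epithelia (-4.08 ± 0.27), the uroplakin Upk1a (-3.92 ± 0.11), the imprinted gene Zim1 (-3.77 ± 0.15), Mab21l4 (-3.36), Upk3bl (-3.33) and the membrane protein Mal (-3.02). Pou5f1 (0.67, adjusted p = 0.000755), Nanog (0.58), Sox2 (0.61, 0.00373) and Klf4 (0.32, 0.00639) had positive differences. So had Stra8 (0.48, 0.0334), Dazl (2.23) and Xist (1.24), and Igf2 had a negative one (-1.40). The difference was 0.45 ± 0.21 for Zfp42 (0.0927), 0.24 ± 0.12 for Gfra1 (0.122) and -0.17 ± 0.12 for Ddx4 (0.251).

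Pluripotency genes had positive differences in 18 of 29 and negative ones in 2 (19 and 2 adjusted over the list alone, median 0.42, camera adjusted p = 0.000232), with Nr0b1 at 1.80. The fibroblast list was positive in 20 of 22 and negative in 2, also adjusted over the list alone (median 1.48, 2.12e-13), with Dcn at 3.57. The stress list was positive in 12 of 18 with 0 negative (13 adjusted over the list alone, median 0.64, 0.000134), and the endoderm and extraembryonic list in 16 of 27 with 8 negative, also adjusted over the list alone (median 0.53, 0.0046). Trophectoderm genes were negative in 12 of 16 and positive in 1 (13 and 1 adjusted over the list alone, median -0.66, 1.64e-05), with Krt7 at -2.48. Retinoid response genes were positive in 8 of 15 and negative in 2, also adjusted over the list alone (median 0.62, 0.0495), with adjusted p = 0.198 with an estimated correlation and 0.349 with dim genes left out. Germline and meiotic genes were positive in 17 of 33 and negative in 5 (19 and 5 adjusted over the list alone, median 0.31, 0.0479), with adjusted p = 0.164 with an estimated correlation and 0.132 with dim genes left out. Cell cycle genes were positive in 12 of 26 and negative in 5 (13 and 5 adjusted over the list alone, median 0.29, 0.0472), with adjusted p = 0.308 with an estimated correlation and 0.414 with dim genes left out. Maternally expressed imprinted genes were called with dim genes left out (median -0.42, 0.0275).

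Of the 9110 genes 4829 were positive and 4281 negative, a majority that turned with arrays centred (4497 and 5084) or quantile normalised (4113 and 5157). Of these 9110, 1348 differed at least 2-fold, 1083 positive and 265 negative. The call of Stra8 was lost without ES replicates 1 (adjusted p = 0.0534), 2 (0.0528) or 3 (0.0613), adult replicates 1 (0.0610) or 3 (0.0513), differentiated ES replicate 2 (0.0828) or differentiated adult replicates 2 (0.0571) or 3 (0.0545), and that of Klf4 after quantile normalisation (0.330). Zfp42 was called without differentiated adult replicate 3 (0.70, 0.000336), and Gfra1 without ES replicate 3 (0.0253) or adult replicate 3 (0.0175).

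After differentiation, adult 129SV cells had higher levels of pluripotency, cell cycle and fibroblast genes than ES cells and lower levels of trophectoderm genes. The nuclear export gene Nxf3 (2.59 ± 0.11, adjusted p = 6.61e-11), the noradrenaline transporter Slc6a2 (2.30 ± 0.12), the growth factor Vegfd (2.12 ± 0.07) and the retinaldehyde dehydrogenase Aldh1a1 (2.03 ± 0.12) were among the highest. The lowest were Scel (-3.79 ± 0.19, adjusted p = 4.01e-10), Zim1 (-3.66 ± 0.11) and Upk1a (-3.46 ± 0.08), and Grb10 (-2.88 ± 0.05, adjusted p = 3.26e-15) and Igf2r (-2.58 ± 0.05) were also among the 10 lowest. The groups of 3 arrays did not overlap for these genes. Pou5f1 was higher by 0.63 (adjusted p = 7.83e-05), Nanog by 0.48, Sox2 by 0.43 (0.00558), Zfp42 by 0.79, Stra8 by 0.52 (0.0038) and Dazl by 0.69. Gfra1 fell by 0.36 and Igf2 by 2.06, while Klf4 (0.15 ± 0.06, 0.0718), Ddx4 (-0.13 ± 0.08, 0.253) and Xist (0.05 ± 0.13, 0.822) did not pass.

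Pluripotency genes were higher in 19 of 29 and lower in 3 (22 and 3 adjusted over the list alone, median 0.48, camera adjusted p = 1.36e-07), with Utf1 at 1.22 and Tdgf1 at 1.20. Cell cycle genes were higher in 16 of 26 and lower in 1 (17 and 1 adjusted over the list alone, median 0.30, 9.95e-07), with Mcm5 at 1.07. Fibroblast genes were higher in 16 of 22 with 0 lower (17 and 1 adjusted over the list alone, median 0.76, 1.48e-10), with the collagens Col1a2 at 1.79 and Col5a2 at 1.66. Trophectoderm genes were lower in 10 of 16 and higher in 1, also adjusted over the list alone (median -0.36, 8.74e-05), with Krt7 at -1.63 and the transcription factor Elf5 at -1.51. Maternally expressed imprinted genes were lower in 9 of 19 and higher in 1, also adjusted over the list alone (median -0.19, 5.35e-05), with adjusted p = 0.107 with an estimated correlation. Macrophage and blood genes were lower in 3 of 13 with 0 higher, also adjusted over the list alone (median -0.19, 0.007), with adjusted p = 0.085 with an estimated correlation, and the receptor Csf1r fell by 1.02. Spermatogonial stem cell genes were higher in 8 of 19 and lower in 2, also adjusted over the list alone (median 0.11, 0.026), with adjusted p = 0.106 with an estimated correlation and 0.136 with dim genes left out. Chromatin and DNA methylation genes were higher in 12 of 22 and lower in 1 (12 and 2 adjusted over the list alone, median 0.16, 0.00209), with adjusted p = 0.224 with an estimated correlation and 0.0717 with dim genes left out. Y-linked genes were higher in 4 of 7 with 0 lower (5 and 1 adjusted over the list alone, median 0.40, 0.0479), with adjusted p = 0.107 with an estimated correlation and 0.746 with dim genes left out.

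Between differentiated adult and ES cells 6419 genes were called, 3874 higher and 2545 lower, and 253 changed at least 2-fold, 135 higher and 118 lower (364 and 139 with every probe set tested); the interval of 97.4% of genes lay within a 2-fold change. In a fit to these 6 arrays alone 3537 genes were called and Sox2 was not (adjusted p = 0.107), and 4244 were called when the replicate number was a block as well, a setting chosen after the data were seen. Klf4 was called without ES replicate 3 (0.21, adjusted p = 0.0133), the array that stood apart from its group, and Ddx4 without adult replicate 1 (-0.22, 0.0474).

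Between backgrounds, ES Stra8 cells had lower levels of interferon-induced genes than ES 129SV cells. Ifit3 (-4.66 ± 0.09), the antiviral protein Rsad2 (-4.49 ± 0.10) and Irf7 (-4.40 ± 0.09, adjusted p = 3.41e-15) were among the 10 lowest. The nuclear receptor Nr1h5 was the highest (4.61 ± 0.10, adjusted p = 5.52e-15), followed by Sycp3 (2.65 ± 0.18), Hhip (2.61 ± 0.12) and the Nodal antagonist Lefty2 (2.56 ± 0.07), and the aquaporin Aqp3 was higher by 2.42. The 3 arrays of each group did not overlap for these genes. Nanog was higher by 0.28 (0.000176), Sox2 by 0.29 (0.0458), Zfp42 by 0.56 and Ddx4 by 0.46. Pou5f1 fell by 0.32 (0.0137), Stra8 by 0.69, Gfra1 by 0.82, and Dazl by 1.45, Igf2 (-1.92) and Xist (-1.25) were lower, and Klf4 did not pass (0.14 ± 0.06, 0.0756).

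Fibroblast genes were lower in 20 of 22 with 0 higher (21 adjusted over the list alone, median -1.03, camera adjusted p = 7.57e-16), led by collagen Col3a1 (-1.91). The endoderm and extraembryonic list was lower in 15 of 27 and higher in 1 (15 and 2 adjusted over the list alone, median -0.30, 4.74e-05), and the retinoid response in 10 of 15 with 1 higher (12 and 1 adjusted over the list alone, median -0.46, 0.000441). Pluripotency genes were higher in 16 of 29 and lower in 3 (18 and 3 adjusted over the list alone, median 0.29, 8.74e-05), with Lefty1 at 1.90 and Esrrb at 1.06. Mesoderm genes were lower in 9 of 21 and higher in 1, also adjusted over the list alone (median -0.17, 0.00414), with adjusted p = 0.191 with an estimated correlation, and the receptor Pdgfra fell by 1.49. In the germline and meiotic list 16 of 33 were higher and 7 lower, also adjusted over the list alone (median 0.22, 0.0316), with adjusted p = 0.126 with an estimated correlation and 0.118 with dim genes left out. Hox genes were lower in 15 of 37 and higher in 2 (16 and 3 adjusted over the list alone, median -0.20, 0.0242), with adjusted p = 0.198 with an estimated correlation and 0.0573 with dim genes left out. Cell cycle genes were higher in 13 of 26 and lower in 4, also adjusted over the list alone (median 0.12, 0.0493), with adjusted p = 0.311 with an estimated correlation and 0.172 with dim genes left out.

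In this comparison 8248 genes were called, 4255 higher and 3993 lower, and 905 changed at least 2-fold, 224 higher and 681 lower (801 and 835 with every probe set tested). The call of Sox2 was lost without any 1 of the 6 arrays (adjusted p = 0.104, 0.118 and 0.0619 without 129SV replicates 1, 2 and 3, and 0.0821, 0.0921 and 0.108 without Stra8 replicates 1, 2 and 3), and that of Pou5f1 without 129SV replicate 1 (0.0587) or with arrays centred (0.0517). Klf4 was called with arrays centred (0.20, adjusted p = 0.00897).

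Adult Stra8 cells had higher levels of meiotic genes than adult 129SV cells. Nr1h5 (5.84 ± 0.10, adjusted p = 1.22e-15), the iron-siderophore carrier Lcn2 (4.04 ± 0.08), Sycp1 (3.38 ± 0.06), Srgn (3.21 ± 0.08) and the sperm tail dynein Dnah8 (2.88 ± 0.07) were among the 10 highest. Calcoco2 (-2.87 ± 0.13, adjusted p = 2.95e-11), Enpp3 (-2.75 ± 0.08), AU015836 (-2.43 ± 0.07) and the arginine sensor Castor1 (-2.37 ± 0.07) were among the 10 lowest, and no array of either group overlapped the other for these genes. Ddx4 was higher by 1.00, Dazl by 0.56 and Xist by 0.59. Pou5f1 fell by 0.30 (0.0147), Nanog by 0.35, Zfp42 by 0.43 (0.0249) and Stra8 by 0.70, while Sox2 (0.13 ± 0.11, 0.338), Klf4 (-0.07 ± 0.06, 0.348), Gfra1 (0.07 ± 0.09, 0.538) and Igf2 (-0.07 ± 0.05, 0.263) did not pass.

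Germline and meiotic genes were higher in 22 of 33 and lower in 4 (23 and 4 adjusted over the list alone, median 0.60, camera adjusted p = 2.51e-06), with Smc1b at 2.36 and Sycp2 at 1.87. The endoderm and extraembryonic list was higher in 14 of 27 and lower in 3, also adjusted over the list alone (median 0.23, 0.00179), with Lama1 at 1.32. Fibroblast genes were higher in 14 of 22 and lower in 4, also adjusted over the list alone (median 0.41, 0.00126), with adjusted p = 0.0724 with an estimated correlation and 0.0505 with dim genes left out, and Dcn rose by 2.34. Stress genes were higher in 10 of 18 and lower in 4, also adjusted over the list alone (median 0.23, 0.0135), with adjusted p = 0.102 with an estimated correlation and 0.0652 with dim genes left out, and Chac1 rose by 2.77. Trophectoderm genes were lower in 11 of 16 and higher in 1, also adjusted over the list alone (median -0.35, 0.0251), with adjusted p = 0.0631 with an estimated correlation and 0.0597 with dim genes left out. In all, 10173 genes were called, 4824 higher and 5349 lower, a balance that turned with dim genes left out (4480 and 4126). At least 2-fold were 974, 708 higher and 266 lower (1705 and 728 with every probe set tested). The call of Pou5f1 was lost without 129SV replicate 3 (adjusted p = 0.0548) and that of Zfp42 without 129SV replicates 1 (0.0679) or 3 (0.0510) or Stra8 replicate 1 (0.0699), while Igf2 was called without Stra8 replicate 1 (-0.13, 0.0400) or after quantile normalisation (-0.14, 0.0132).

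**Figure D4:**
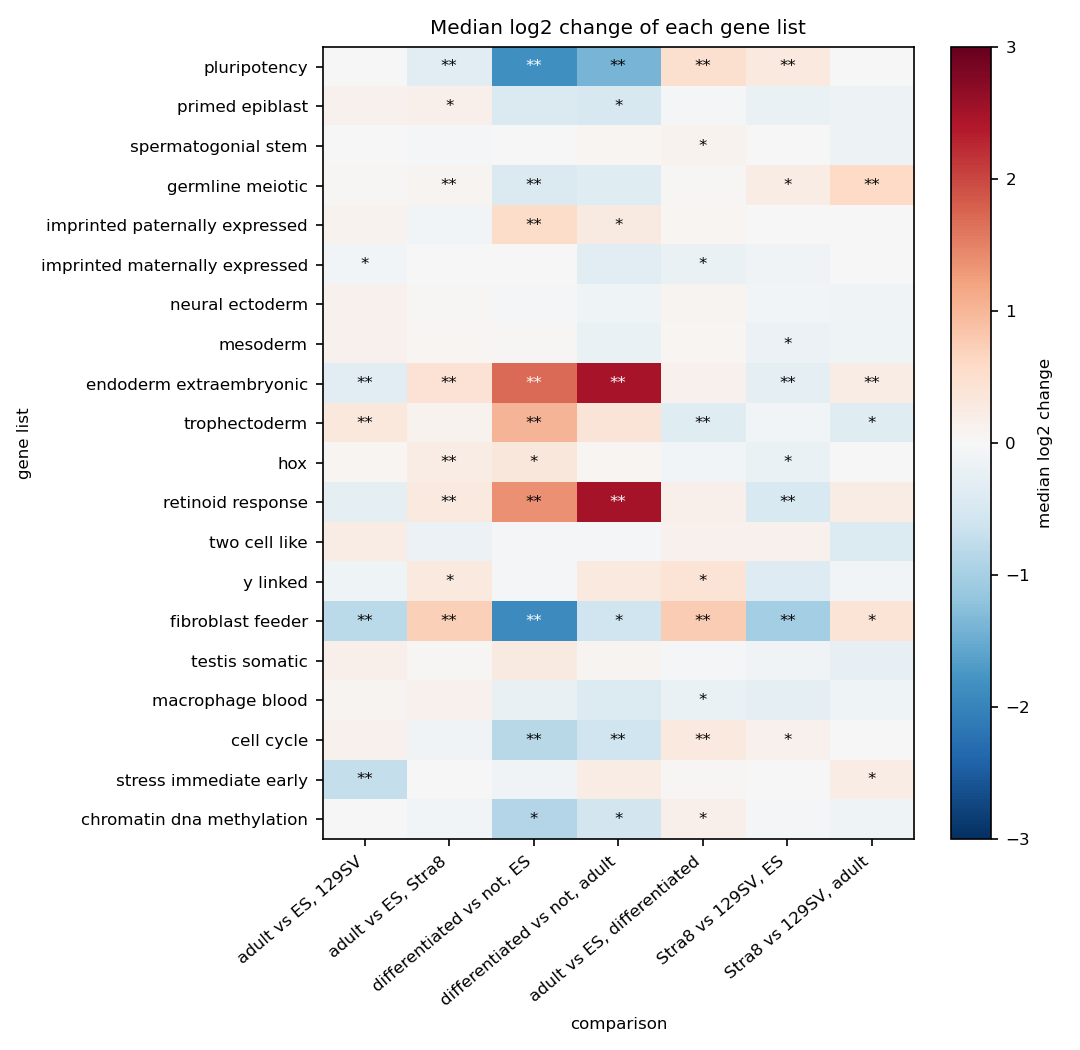
Median log2 change of each of the 20 gene lists (lines) in the 7 comparisons of group pairs (columns), with 1 star for a camera adjusted p under 0.05 and a pair of stars where the call also held with an estimated correlation. The fibroblast list had a median of -0.81 between adult and ES 129SV cells and 0.73 between adult and ES Stra8 cells.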

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

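The tests of explanations for the 3 patterns below were chosen only after the results had been seen, while the other splits of the arrays were planned. The effect of origin, which is the difference between adult and ES groups, differed between backgrounds for 8588 genes, by a test of the difference itself. The genes furthest apart were Cxcl10 (6.29), Srgn (6.07), Ifit3 (6.01), Irf7 (5.89), Cubn (5.49) and Ifit3b (5.46) on the positive side. On the negative side they were Calcoco2 (-3.71), Dppa3 (-3.05), Tubb3 (-2.74), Enpp3 (-2.68), Pnma5 (-2.60) and AU015836 (-2.55). Of the genes always given, Nanog (-0.64), Zfp42 (-0.99), Gfra1 (0.89), Ddx4 (0.54), Dazl (2.01), Igf2 (1.85) and Xist (1.84) differed. The lists that differed had medians of -0.24 for pluripotency, 0.013 for germline and meiosis, 0.78 for endoderm, 0.18 for Hox genes, 0.53 for the retinoid response, 1.53 for fibroblasts and 0.62 for stress genes. With an estimated correlation the calls of pluripotency (adjusted p = 0.177), germline and meiosis (0.150), Hox genes (0.221) and the retinoid response (0.0886) were lost, the last 3 also with dim genes left out (0.136, 0.184 and 0.0590), and the germline median turned to -0.03 with arrays centred.

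The response to differentiation differed between origins for 9110 genes, again by a test of the difference. This difference and that between backgrounds share the gap between undifferentiated ES and adult 129SV cells, so they are not independent findings. For Cxcl10 the mean was 13.14 in ES and 7.295 in adult 129SV cells, against 8.04 and 8.855 after differentiation. The most positive were Cxcl10 (6.66), Ifit3 (5.80), Irf7 (5.04), Iigp1 (5.02), Ifit3b (4.95) and Trim30a (4.92). The most negative were Scel (-4.08), Upk1a (-3.92), Zim1 (-3.77), Mab21l4 (-3.36), Upk3bl (-3.33) and Mal (-3.02). Pou5f1 (0.67), Nanog (0.58), Sox2 (0.61), Klf4 (0.32), Stra8 (0.48), Dazl (2.23), Igf2 (-1.40) and Xist (1.24) differed as well. The list medians were 0.42 for pluripotency, 0.31 for germline and meiosis, 0.53 for endoderm, -0.66 for trophectoderm, 0.62 for the retinoid response, 1.48 for fibroblasts, 0.29 for the cell cycle and 0.64 for stress genes. The calls of germline and meiosis (adjusted p = 0.164), the retinoid response (0.198) and the cell cycle (0.308) were lost with an estimated correlation, and also with dim genes left out (0.132, 0.349 and 0.414).

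Signal also appeared in the 13767 probe sets without a single gene symbol, which no comparison of genes used. Called at least 2-fold were 683 of them between adult and ES 129SV cells, 197 between adult and ES Stra8 cells and 185 between differentiated adult and ES cells. Differentiation changed 1316 in ES and 2080 in adult cells, and the backgrounds differed in 624 for ES and 1301 for adult cells. Samples far from their group were not looked for by rule, because groups of 3 are too small for it.

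Other splits of the arrays were fitted with the compared arrays alone. For the difference between backgrounds 2 of 100 drawn reassignments of 12 arrays, the real one included, gave as many genes as the real 9644. The other was the one that exchanges whole groups of 1 origin (11458), and the highest of the rest was 5376. For the response to differentiation 2 of 100 gave as many as the real 7917. Again the other exchanged whole groups (11665), and the highest of the rest was 5974. These draws mix groups that differ without any difference of effects, so they do not test that difference itself and exclude chance for neither result. They show only that the arrays of a group within an origin belong together. For the 7 comparisons of group pairs, 10 splits of 6 arrays are too few for a share under 0.05. The real split was the 1 that gave as many genes, with 9466 for adult against ES 129SV, 7086 for adult against ES Stra8, 9827 and 11303 for differentiation of ES and adult cells, 3537 for differentiated adult against ES, and 9667 and 10459 for the backgrounds of ES and adult cells; the highest other split gave 0 in each. For differentiated adult against ES cells, 4 splits part as many pairs as the real one, and the others among them also gave 0.

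Interferon-induced genes were high in ES 129SV cells. A larger share of fibroblast-like cells would bring fibroblast genes along, but the median interferon gene lay 2.43 above its level in adult Stra8 cells, while the highest fibroblast gene lay 1.53 above and the median one 0.33. Of the 34 interferon genes 25 exceeded that highest fibroblast gene. This argues against more cells of a kind alike in both groups as the whole cause. Fibroblast-like cells with an interferon response in ES 129SV cultures alone were not tested. The list was written after its genes had been seen as high in this group, so its median is high by selection. A second quantile normalisation left the list median at -2.66 with 34 genes still called lower. This argues against remaining differences between the array distributions as the cause. The values had already passed RMA, so scaling within RMA was not tested. What stays open is a difference of cell state, line or culture, which may go with this group, since the labels do not say how many lines or cultures it holds; a biological difference was not tested.

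Maternally expressed imprinted genes, a list whose call was lost with an estimated correlation (adjusted p = 0.107), were lower in differentiated adult 129SV than in ES cells in 9 of 19 members, all named here after their values were seen: Grb10 (-2.88), Igf2r (-2.58), Zim1 (-3.66), Cdkn1c (-1.04), Osbpl5 (-0.90), Ppp1r9a (-0.52), Slc22a18 (-0.32), Kcnq1 (-0.31) and Klf14 (-0.23). Of these, 4 (Grb10, Igf2r, Cdkn1c and Osbpl5) were lower before differentiation too. In adult against ES Stra8 cells their median was 0.31 with 0 lower and 3 higher. A decrease of these 4 genes in both adult cell types was thus not seen. The fibroblast list rose in adult Stra8 cells (median 0.73) and fell in adult 129SV cells (-0.81). Another cell mix could therefore hide a shared decrease, and a shared state cannot be told apart. Other maternally expressed genes were lower in adult than in ES Stra8 cells, Zim1 (-0.64), Meg3 (-0.84) and Rian (-1.12). So were 40 of the 42 genes of the Dlk1-Dio3 list, which covers 1 region and includes Meg3 and Rian. A second quantile normalisation left these 9 members at a median of -0.99 with 9 still called, while the median of the whole list was -0.16. This argues against remaining differences between the array distributions as the cause of their decrease, but scaling within RMA was not tested. Another mix of cell types after differentiation cannot be told apart: 4 members were lower before it, and their median of -0.83 there is negative by their selection, while the fibroblast list differed between the same groups. Whether imprints differ between the cells stays open, since no methylation was measured, and paternally expressed imprinted genes were not called between the same differentiated groups (median 0.05, adjusted p = 0.649), with Igf2 lower (-2.06).

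Fibroblast genes were lower in adult 129SV and higher in adult Stra8 than in ES cells. For Stra8 a larger share of fibroblast-like cells in the adult samples is a candidate explanation: 22 of 22 members rose, the lowest, Fn1 (named after its value was seen), by 0.20, with a standard deviation over the list of 0.22. For 129SV a smaller share cannot be told apart: 17 of 22 fell (median -0.81), while 2 rose, S100a4 furthest by 1.23 (named after its value was seen), and the stem cells may express a few such genes themselves. A second quantile normalisation left the difference between backgrounds at a median of 1.48. This argues against remaining differences between the array distributions as the cause, but scaling within RMA was not tested. Whether the cells themselves express these genes or feeder cells were present may differ by group and stays open: 13 of the 22 lay above the median of all gene values in both differentiated groups, and feeders are not mentioned.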

How the results depend on the processing

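The fit with the replicate number as a block to the 6 arrays of the differentiated groups, and the interferon, hypoxia and Dlk1-Dio3 lists, were chosen only after the data had been seen; the other settings were planned. Only the highest, lowest and always given genes were followed over settings, and none of their called changes turned sign. The settings were the block, the compared arrays alone, both scalings, averaged probe sets and leaving out arrays. No direction of a called list turned with an estimated correlation, the block, dim genes left out or fry. The median of the germline and meiotic list between backgrounds turned from 0.013 to -0.03 with arrays centred. The larger side of the called genes also turned, with causes not tested. For adult against ES 129SV (4583 higher, 4613 lower) it turned with the block (4625, 4595), array weights (5002, 4891), centring (5288, 4319), quantile normalisation (5450, 4226), every probe set (7447, 6396) and these arrays alone (4889, 4577). For differentiated ES cells (5553, 5452) it turned with array weights (6371, 6557), dim genes left out (4340, 4849) and these arrays alone (4880, 4947). Leaving out dim genes turned it for the difference between backgrounds (3943, 3937), differentiated adult cells (4882, 4640) and the backgrounds of adult cells (4480, 4126), and both scalings for the response by origin (4497, 5084 and 4113, 5157). At least 2-fold, every probe set turned it for Stra8 (136, 242) and differentiated ES cells (2081, 1806), and quantile normalisation gave 168 higher and 599 lower for adult against ES 129SV. Leaving out some single arrays turned the larger side as well for adult against ES cells of both backgrounds, the difference between backgrounds, differentiated ES cells and the backgrounds of adult cells, so these near-even splits of called genes give no direction. Outside leaving out arrays, 182 of the counts, similarities and list totals stayed within their limits and 29 moved. The limit for counts was a ratio to the main count and is wide. For adult against ES Stra8, 7086 genes in place of 5638 lay within it. Leaving out each array in turn moved none of 186 past these limits. It gave 8251 to 8653 genes for adult against ES 129SV (9196 with all arrays) and 4550 to 4917 for adult against ES Stra8 (5638). For differentiated adult against ES it gave 5329 to 6768 (6419 with all arrays). Genes of the same sign in both backgrounds numbered 723 to 903 (979 with all arrays). Testing every probe set raised counts by its construction, 35556 probe sets in place of 19938 genes. It gave 13843 called and 1562 at least 2-fold for adult against ES 129SV, 378 at least 2-fold for Stra8, 3098 for the difference between backgrounds, and 17196 and 3887 for differentiated ES cells. For differentiated adult cells it gave 19344 and 4756, for the response by origin 2532 at least 2-fold, for differentiated adult against ES 503, for the backgrounds 1636 in ES cells and 15651 and 2433 in adult cells, and 10970 moved the same way in both differentiations. Among those at least 2-fold, the share higher was 29.2% in place of 12.9% for adult against ES 129SV, 36.0% in place of 64.7% for Stra8, 58.4% in place of 73.4% for the difference between backgrounds, 53.5% in place of 41.5% for differentiated ES cells, 72.4% in place of 53.4% for differentiated adult against ES, and 49.0% in place of 24.8% for the backgrounds of ES cells. Array weights gave 8690 genes for adult against ES Stra8 and 1714 of the same sign in both backgrounds; the estimate of the weights stopped before it reached its tolerance, and the cause was not tested. The 6 arrays of the differentiated groups alone gave 3537 genes, and 4244 with the block, against 6419 in the main fit. The main fit takes 1 spread per gene for all groups, while the mean r within a group was lowest in differentiated ES cells (0.993). A fit to 6 arrays also has fewer degrees of freedom, and the cause was not tested. Leaving out dim genes lowered the mean r to 0.904 and 0.971 between ES and adult cells of 129SV and Stra8, 0.958 after differentiation, and 0.762 and 0.792 across differentiation of ES and adult cells, and with every probe set the mean r was 0.988 for Stra8, 0.980 after differentiation, and 0.946 and 0.943 across differentiation, and the cause was not tested. Of the 180 list tests, 40 were called with an estimated correlation, 151 by fry, which asks another question, and 50 with dim genes left out, against 68. Over these settings and lists 578 results kept their side of the threshold, 85 gained a call and 48 lost it. For the named genes that were followed, 1301 results kept their side, 9 gained and 5 lost a call. When arrays were left out 1811 kept it, 8 gained and 35 lost it. Among these genes the replicate block changed no other call than that of Klf4 between backgrounds (adjusted p = 0.0465, over its alternatives 0.0125 to 0.0465 where it was called). In the comparisons other than differentiated adult against ES, arrays were taken to share only a number. There the r of arrays with the same number was not positive in all 3 pairs. In no comparison of group pairs, differentiated adult against ES included, did all 3 arrays correlate best with their own number. In the other comparisons the block gave between 5589 and 11962 genes. No scaling moved the median of all genes by over 0.1 from its value as reported. Groups of 3 arrays limit the detection of small changes, and signal over background was not used here, so genes too dim to be measured could not be set apart from unchanged ones.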

Other observations

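The lists in these paragraphs were written only after the named genes had been seen, so their adjusted p-values, over 27 tests, are no independent evidence, and no test of an explanation was run on the hypoxia and Dlk1-Dio3 lists. Hypoxia-induced genes were lower in adult than in ES 129SV cells in 29 of 29 members (median -1.18, camera adjusted p = 1.73e-24, 9.14e-05 with an estimated correlation). Named after their values were seen, the vasodilator peptide Adm changed by -3.60 ± 0.06, the growth factor Pgf by -3.79 ± 0.08 and the mitophagy receptor Bnip3 by -2.02 ± 0.05. In adult against ES Stra8 cells 15 rose and 2 fell (median 0.18, adjusted p = 9.10e-06), and Adm rose by 0.92. ES Stra8 cells were lower than ES 129SV cells in 28 members with 0 higher (median -1.77, adjusted p = 3.58e-27). On differentiation 25 fell and 2 rose in ES cells (median -1.20, adjusted p = 7.11e-12), while in adult cells 14 rose and 7 fell (median 0.18, adjusted p = 0.0114), a call lost with an estimated correlation (0.164). After differentiation 15 were higher and 3 lower in adult than in ES cells (median 0.17, adjusted p = 0.000882), also lost that way (0.0724). Between adult cells of both backgrounds 11 were higher and 13 lower in Stra8, without a call (median -0.02, adjusted p = 0.898).

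The list of the imprinted Dlk1-Dio3 region on chromosome 12 holds 42 measured genes, which are microRNA genes with Meg3, Rian, Rtl1 and Dlk1. In adult against ES Stra8 cells 40 fell and 0 rose (median -1.04, camera adjusted p = 7.81e-30, 3.83e-05 with an estimated correlation), among them the noncoding RNAs Meg3 (-0.84) and Rian (-1.12). In 129SV cells 13 rose and 3 fell without a call (median 0.17, adjusted p = 0.0973), with Meg3 at 0.45 and Rian at -0.97. After differentiation 24 were higher and 1 lower in adult than in ES 129SV cells (median 0.38, adjusted p = 1.74e-05, 0.0223 with an estimated correlation). The difference between backgrounds was negative in 40 and positive in 1 (median -1.21, adjusted p = 2.89e-14). Differentiation raised 38 with 0 down in ES cells (median 0.86, adjusted p = 1.66e-10) and 39 with 0 down in adult cells (median 1.08, adjusted p = 4.47e-12). ES Stra8 cells had higher values than ES 129SV cells in 41 members and lower in 1 (median 1.40, adjusted p = 1.67e-23). Adult Stra8 cells had higher values than adult 129SV cells in 14 and lower in 4 (median 0.14, adjusted p = 0.0446, lost with an estimated correlation at 0.240). Most of these probe sets read transcripts of microRNA genes, so their values are not levels of mature microRNAs.

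Interferon-induced genes were lower in adult than in ES 129SV cells in 34 of 34 members (median -2.71, camera adjusted p = 6.17e-34). In adult against ES Stra8 cells 18 rose and 1 fell (median 0.25, adjusted p = 2.41e-06). On differentiation 34 fell in ES cells (median -2.99, adjusted p = 1.78e-23), while in adult cells 15 rose and 10 fell without a call (median 0.07, adjusted p = 0.186). After differentiation 6 were higher and 9 lower in adult than in ES cells, without a call (median -0.06, adjusted p = 0.611). Stra8 cells were lower than 129SV cells in 34 members among ES cells (median -2.75, adjusted p = 1.45e-35), and higher in 18 and lower in 8 among adult cells (median 0.26, adjusted p = 0.00514).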
